A study of Drosophila melanogaster with 6 samples.

How the data were processed

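BEAF-32 (boundary element-associated factor), an insulator protein of Drosophila, was profiled by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in wing imaginal discs. The discs are the larval epithelial sacs that form the adult wing and the adjoining body wall. They came from the third larval instar of the wild-type strain Oregon R, spelled Orgon R in the labels. Per the labels' protocols, 200 discs were dissected and fixed with 1% formaldehyde for 10 min. The chromatin was sonicated to fragments of 200 to 500 bp and precipitated with an antibody against the isoform BEAF-32B. Amplified libraries were size-selected at 200 to 300 bp by gel extraction. The sample titles define 4 ChIP libraries and 2 libraries of input chromatin.

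The authors deposited 1 peak list for the whole series, with 3 columns and no header: chromosome, start and end. It holds no score, height, coverage or p-value per peak, and no value per library. Bowtie 0.12.5 is named for all 6 libraries, per the submitters' processing notes. The peak caller, its threshold, the use made of the input libraries, any pooling of the 4 ChIP libraries and the genome build are not given in the sources used here. The chromosome names of the deposited list, which include 2LHet and Uextra, are those of Release 5 of the Drosophila melanogaster assembly. The gene table at hand belongs to Release 6, so it was not joined to the peaks. Positions are printed as deposited, with starts counted from 1.

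No genome sequence or annotation of the build was used here. For that reason the planned comparisons of promoters, annotation classes, divergent gene pairs, fixed gene lists, sequence motifs and 5-base words were not run. The comparison of peak scores was not run because the list has no score. The planned arm length was that of the assembly. It was replaced by the other length listed in the plan, that from coordinate 0 to the end of the last peak of the arm, which is at most the true length. Where a score was to rank peaks, width was used, as planned for a list without scores.

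The depth of the libraries is unknown, so neither the sensitivity of the peak calls nor their agreement between replicates was measured. Intervals and p-values below describe this 1 list: they cover the counting of peaks or their placement along the arms, and not the spread between libraries. Sequence repeats, copy number and the unknown calling threshold can all change which sites enter such a list.

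Peaks per arm were compared with the share of the summed length of the 6 arms (2L, 2R, 3L, 3R, 4 and X) by a two-sided exact binomial test, with Benjamini-Hochberg adjustment over the 6 arms. Densities have exact Poisson 95% intervals. The binomial test takes peaks as independent, so mean counts in full 1-Mb windows were also permuted between arms (100000 resamples, or exact enumeration for chromosome 4). This addition was chosen after seeing the data. Spacing was compared on the 5 large arms with 1000 random placements of the same peaks on the same arm, without overlap. In a second kind of random list, also added after seeing the data, each peak was moved by up to 250 kb or up to 50 kb, which keeps regional differences in density. The smallest two-sided p that 1000 placements can give is 0.002. The 2 Mb at the centromere end of each arm were compared with all choices of one 2-Mb window per arm, with windows laid from the outermost peak of that end, an exact test over 173030 choices that was also added later. Median widths were compared by permutation of widths between arms (100000 resamples) with bootstrap intervals from 2000 draws. The planned description of widths was a median and range, so these width tests were added later too. Other settings of the end and width tests were adjusted over the same tests as the reported values, and X against single arms over the 4 tests.

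The planned rule for naming single peaks was the 10 widest. Extreme windows, gaps, runs of close peaks and the peaks of chromosome 4 were singled out after their values were seen. Alternatives were the peaks wider than the median (658 bp or more, 1301 peaks), peaks within 500 bp of each other merged (2398 peaks), other arm lengths and placements, and single arms left out.

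The steps were tested on simulated data with the 2570 peaks of the 5 large arms, using the real peak widths for spacing and width. Of 200 lists with randomly placed peaks, 1.5% were called by the median distance between neighbours, in either direction. Of 200 lists with 20% of the peaks moved next to another, 100% were called by the share with another within 5 kb. The 1.5% is therefore not the false-call rate of the share. An X chromosome made 1.25-fold denser was called in 99% of 200 lists, against 5.5% with even density, by the unadjusted binomial test. These lists were counts per arm with peaks drawn independently. The 1-Mb windows of the deposited list had a variance 4.90 times the mean, so these rates do not describe the density test on that list. Shuffled widths were called in 4% of 100 lists, and an X with peaks narrower by 30 bp in 63% of 100. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.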

Results

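The distribution of BEAF-32 in the wing disc was described by 2609 peaks on 13 sequences, together covering 1.88 Mb. No 2 peaks overlapped. The median peak was 657 bp wide, with quartiles of 520 and 836 bp and a range of 279 to 2442 bp. Peaks wider than 1000 bp numbered 378, or 14.5% of the list. The 6 chromosome arms carried 2575 peaks (98.7%), and 34 peaks lay on other sequences. The labels do not say how the 4 ChIP libraries and 2 input libraries entered this list, which has no value per library. The spread between replicates and the background in the input were therefore not measured, and sequencing depth is unknown.

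The first comparison asked how BEAF-32 peaks were shared among the chromosome arms. The X chromosome carried 577 peaks in 22.2 Mb, or 26.0 peaks per Mb (Poisson 95% interval 23.9 to 28.2), against 20.8 per Mb on all other arms together. Arm 2L was the sparsest of the 5 large arms, with 383 peaks and 16.7 per Mb (15.1 to 18.5) where an even spread gave 498 peaks. Chromosome 4, the small and largely heterochromatic dot chromosome, held 5 peaks where 22.9 were expected, or 4.75 per Mb (1.54 to 11.1).

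The autosomal arms 2R, 3L and 3R lay between 2L and X. Arm 2R had 499 peaks and 23.8 per Mb (21.8 to 26.0). Arm 3L had 504 peaks and 21.7 per Mb (19.8 to 23.7). Arm 3R had 607 peaks and 21.8 per Mb (20.1 to 23.6). The density ratios of 3L and 3R to the other arms were 0.99 and 1.00.

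By the exact binomial test with Benjamini-Hochberg adjustment over 6 arms, X (1.25-fold the density of the other arms, adjusted p = 1.31e-05), 2L (0.73-fold, adjusted p = 1.94e-08) and chromosome 4 (0.22-fold, adjusted p = 2.62e-05) departed from an even spread. In the same exact test, 2R also passed the threshold of 0.05, narrowly (1.11-fold, adjusted p = 0.0484), and 3L and 3R did not (adjusted p = 0.963 for both). The density varied between windows more than counting error allows. Over the 6 arms together, 1-Mb windows held 21.9 ± 10.4 peaks (SD, 115 windows), a variance 4.90 times the mean. Within single large arms the variance was 2.97 (X) to 7.05 (2R) times the mean. When all 115 windows were permuted between arms, no arm passed the adjusted threshold. The adjusted permutation p was 0.0938 for X, with 26.2 ± 8.81 peaks per window (SD, 22 windows) against 20.9 elsewhere. It was 0.0713 for 2L, with 17.0 ± 10.7 (SD, 22 windows) against 23.1. For 2R the adjusted permutation p was 0.562. Chromosome 4 has 1 full window, with 4 peaks, and its adjusted exact p was 0.157. This two-sided test of 1 window also counts the densest windows as extreme, so no count there could have passed the adjusted threshold. It therefore cannot tell whether chromosome 4 is depleted. At unadjusted values, X (p = 0.0313) and 2L (p = 0.0119) were below 0.05 in the window permutation test. Among the peaks of 658 bp or more, the X density was 1.13-fold that of the other arms (adjusted p = 0.104, exact binomial test).

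**Figure D1:**
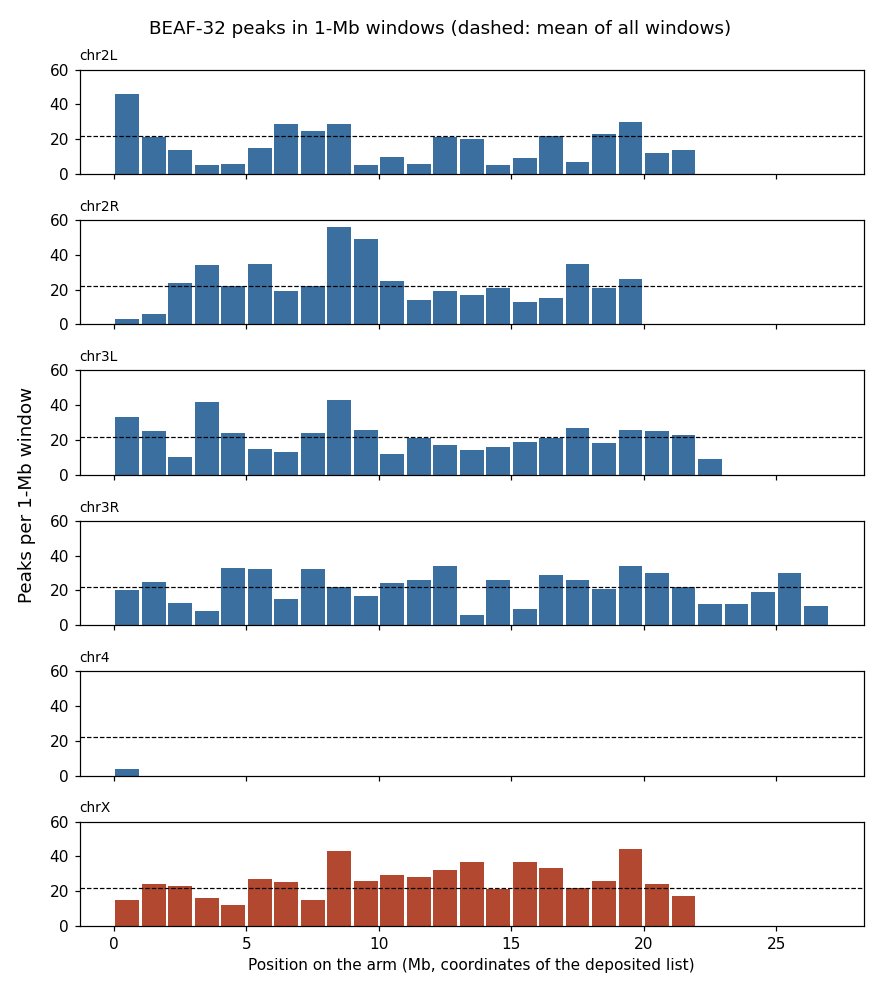
Number of BEAF-32 peaks (vertical axis) in each full 1-Mb window along the 6 chromosome arms (horizontal axis, Mb), with X in red and the mean of all windows, 21.9 peaks, as a dashed line. Windows range from 3 to 56 peaks, and the densest pair of neighbouring windows lies on 2R.

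Along the arms, peak-rich and peak-poor regions alternated. The densest 1-Mb window was chr2R:8000001-9000000 with 56 peaks, followed by its neighbour chr2R:9000001-10000000 with 49. The first window of 2L, at the telomere end, came next with 46 peaks, although 2L as a whole was the sparsest large arm. Windows chrX:19000001-20000000 with 44 peaks, chrX:8000001-9000000 and chr3L:8000001-9000000 with 43 each, and chr3L:3000001-4000000 with 42 were of similar density. The sparsest window of the large arms was chr2R:1-1000000 with 3 peaks, at the centromere end. On 2L, windows 3000001-4000000, 9000001-10000000 and 14000001-15000000 held 5 peaks each.

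Between neighbouring peaks of the large arms, the longest stretch without a peak was chr2L:8735947-9572029, 836 kb. Stretches beyond the outermost peaks of an arm were not counted. The next were chr2L:11278764-12000043 (721 kb), chr3L:22070551-22710171 (640 kb, near the centromere end), chr3L:18056772-18665664 (609 kb) and chr3L:4542146-5131468 (589 kb). On X the longest was chrX:21259103-21846594 (588 kb), on 3R chr3R:12904184-13471018 (567 kb) and on 2R chr2R:15615067-16144313 (529 kb). The longest distance between neighbouring midpoints was 837 kb, against 409 kb on average in random placements (95% of placements between 314 and 576 kb, two-sided permutation p = 0.002). With peaks moved by up to 250 kb, the longest distance averaged 774 kb. The observed value was within the range of the moved lists (permutation p = 0.597). Moved lists start from the observed peaks and carry long stretches along. This comparison therefore cannot tell whether regional density accounts for the longest distance.

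The ends of the arms were compared with their interiors, with 2-Mb windows laid from the outermost peak of each end. The 2 Mb nearest the centromere held fewer peaks than the average 2 Mb of the arm on 4 of the 5 large arms: 17 against 48.3 on 2R, 26 against 42.5 on 3L, 37 against 52.4 on X and 23 against 30.7 on 2L. On 3R the values were 45 and 44.5. Counted from coordinate 0 in place of its first peak, the 2R end held 9 peaks against 47.6. Summed over the arms, 148 peaks lay in these windows against 218 ± 33.8 (SD over choices of windows), a ratio of 0.68 (exact p = 0.0207, adjusted p = 0.0413 over both ends). This result is near the threshold and several other settings lose it, with p-values adjusted over both ends. The ratio was 0.82 with 3 Mb (exact p = 0.105, 0.0525 unadjusted) and 0.70 after merging of peaks within 500 bp (exact p = 0.0578). It was 0.77 without 2R (exact p = 0.236), 0.69 without 3L (exact p = 0.123) and 0.67 without X (exact p = 0.0923). With 1 Mb it was 0.52 (exact p = 0.0128). Among the peaks of 658 bp or more it was 0.62 (exact p = 0.0345 before and after adjustment). Adjustment over both ends leaves that value unchanged only if the telomere ends of these wider peaks passed the threshold too. Their ratio and direction are not given here, so the telomere result below holds for the whole list only. The 2 Mb nearest the telomere held 256 peaks against 225 ± 30.7 (ratio 1.14, exact p = 0.323), with 69 on 2L against an average of 34.1 in windows laid from that end, or 2.02-fold.

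The second comparison asked whether BEAF-32 peaks lay nearer to each other than random placement gives. The median distance between neighbouring peak midpoints on the 5 large arms was 16.1 kb, against 31.4 kb in random placements (95% of placements between 30.2 and 32.6 kb). Of 2570 peaks, 1137 had another peak within 5 kb, 44.2% (Wilson 95% interval 42.3 to 46.2%), against 17.6% in random placements (15.7 to 19.5%). The Wilson interval takes peaks as independent, although a close neighbour always counts for both peaks of a pair, so it is likely too narrow. Both differences from random placements had a two-sided permutation p of 0.002, the smallest that 1000 placements can give. They were present on each arm. The share with a neighbour within 5 kb was 52.7% on X against 20.4% in placements, 46.7% on 2R against 18.5%, 44.4% on 3L against 17.1%, 39.4% on 3R against 17.1% and 35.8% on 2L against 13.5%, each with permutation p = 0.002.

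The excess of close pairs fell with distance. Pairs of peaks under 1 kb apart were 7.51 times as frequent as in random placements (129 pairs against 17.2). Pairs 1 to 2 kb apart were 3.99 times as frequent (225 pairs against 56.3), pairs 5 to 10 kb apart 2.47 times, pairs 20 to 50 kb apart 1.48 times and pairs 100 to 200 kb apart 1.06 times. Compared with lists in which each peak was moved by up to 250 kb, the ratios were 3.16 at 1 to 2 kb, 2.62 at 2 to 5 kb, 1.98 at 5 to 10 kb, 1.62 at 10 to 20 kb and 1.20 at 20 to 50 kb. All of these ratios had an adjusted permutation p of 0.002 over 8 distance classes. With peaks moved by up to 50 kb the ratios were lower: 2.21 at 1 to 2 kb, 1.84 at 2 to 5 kb, 1.41 at 5 to 10 kb and 1.17 at 10 to 20 kb, and 0.92 at 20 to 50 kb (adjusted permutation p = 0.003 for each). Moving peaks carries close pairs out to larger distances. Ratios below 1 against moved lists are therefore not read as a lack of pairs. The moved lists ignore peak width and may place peaks over each other, so their class under 1 kb is not comparable with the deposited list.

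Close peaks formed runs. With neighbours linked at up to 5 kb, 1433 peaks of the large arms stood alone, 285 runs had 2 peaks, 88 had 3, and 59 had 4 or more. Random placements gave 1.92 runs of 4 or more on average and 7 at most, and lists with peaks moved by up to 250 kb gave 6.67 on average and 16 at most (permutation p = 0.002 for both). The largest run was chr3L:8668378-8698806, with 13 peaks in 30.4 kb, inside one of the densest windows. The next was chr3R:4627117-4649944 with 11 peaks in 22.8 kb. Runs of 8 peaks lay at chr2R:8811381-8824640, chr3L:627734-640961, chrX:6754148-6765138, chrX:9042505-9054865 and chrX:12629113-12650833. Some neighbouring peaks almost touched: 211 gaps between peak edges were 500 bp or shorter, and the smallest was 7 bp. After merging of peaks within 500 bp, the share with another within 5 kb was still 2.18 times that of random placements (permutation p = 0.002).

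**Figure D2:**
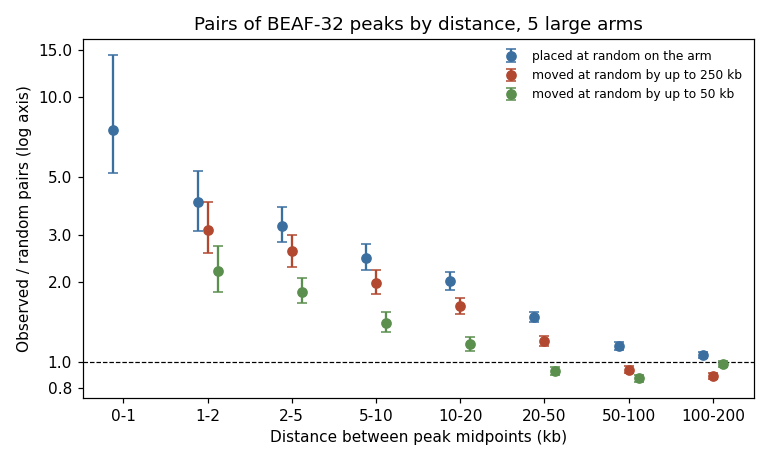
Ratio of observed to random pairs of peaks (vertical log axis) by the distance between midpoints (horizontal axis, kb) on the 5 large arms, for peaks placed at random on the arm (blue) or moved by up to 250 kb (red) or 50 kb (green). Points are ratios to the mean of 1000 random lists and bars the range from 95% of those lists. The class under 1 kb is drawn for random placement only. Against random placement the ratio goes from 7.51 under 1 kb and 3.99 at 1 to 2 kb to 1.06 at 100 to 200 kb.

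The third comparison concerned peak width, the only property of single peaks that the list gives besides position. Peaks on X were narrower than those of the other large arms, with a median of 630 bp (bootstrap 95% interval 608 to 664 bp) against 666 bp, a difference of -36.0 bp (-59.0 to -2.0 bp). The permutation p was 0.00745, and 0.0372 after adjustment over 5 arms. After merging of peaks within 500 bp the difference was -28.5 bp and did not pass the threshold (permutation p = 0.0584, adjusted p = 0.116). Median widths were 653 bp on 2L, 672 bp on 2R, 654 bp on 3L and 679 bp on 3R, and none of these arms differed from the others after adjustment (permutation test, adjusted p from 0.148 to 0.712). When the medians of 1-Mb windows were compared in place of single peaks, the X difference was -21.8 bp (permutation p = 0.191, adjusted p = 0.318). Against single arms, with adjustment over the 4 tests, the X difference was -49.0 bp from 3R (adjusted permutation p = 0.0246). The differences from 2R (-42.0 bp, adjusted permutation p = 0.0589), 2L (-23.0 bp, 0.326) and 3L (-24.0 bp, 0.201) did not pass the threshold.

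**Figure D3:**
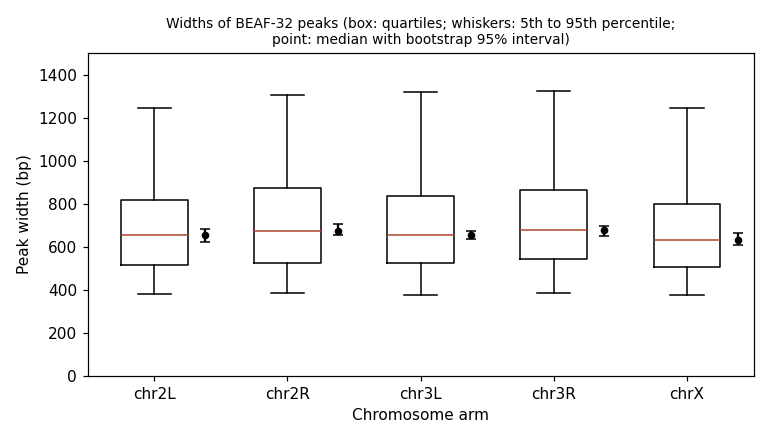
Width of BEAF-32 peaks in bp (vertical axis) on the 5 large chromosome arms (horizontal axis), as boxes of the quartiles with whiskers from the 5th to the 95th percentile, and beside each box the median with its bootstrap 95% interval. The medians run from 630 bp on X to 679 bp on 3R, and the boxes overlap widely.

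The widest peaks were spread over 4 of the 5 large arms. The widest was chr2L:852043-854484, with 2442 bp, within the dense first window of 2L. It was followed by chr3R:19880929-19883318 (2390 bp), chr2R:17030662-17033031 (2370 bp), chr2L:5981359-5983620 (2262 bp) and chr2R:10657895-10660135 (2241 bp). The other 5 of the 10 widest were chr2L:12433632-12435823 (2192 bp), chr2R:8803127-8805300 (2174 bp), chrX:15640583-15642741 (2159 bp), chr3R:21880317-21882408 (2092 bp) and chr3R:9207665-9209753 (2089 bp). On chromosome 4 the 5 peaks were chr4:64229-64623 (395 bp), chr4:528730-529476 (747 bp), chr4:590793-591443 (651 bp), chr4:717330-717694 (365 bp) and chr4:1050767-1051673 (907 bp). The genes at these positions were not analysed here.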

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

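The tests of this part were chosen after the result was seen, except the merging of peaks within 500 bp, which was fixed before the data were examined. The test of merged peaks moved by up to 250 kb was added later, but what would decide it was set down before its value was seen. For the other explanations weighed in this part it was set down afterwards. The list holds 34 peaks outside the 6 chromosome arms, a signal that the comparisons of density, spacing and width among arms did not use. Of these, 25 lay on Uextra, the collection of unplaced scaffolds, 10 of them beyond 28 Mb, 1 lay on U, and 8 lay on the Het sequences, which hold mapped heterochromatin. They were narrower than the peaks of the arms, with a median of 550.5 bp against 658 bp (difference -107.5 bp, bootstrap 95% interval -159 to -42.0 bp, permutation p = 0.0243).

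Peaks lay closer together than random placements gave. Regional differences in density over wide regions are a candidate source, but the share of peaks with another within 5 kb was 44.2% against 23.7% in lists with peaks moved by up to 250 kb, a ratio of 1.87. A caller that splits one site into adjacent peaks may add close pairs, and merging of peaks within 500 bp lowered the ratio from 2.51 to 2.18. Merging removes all such gaps from the list but not from the random lists. The fall is therefore no sign of splitting, and only the excess that remains is read. With merging and movement together the ratio was 1.62 (34.8% against 21.5%, the upper bound of 95% of moved lists being 23.5%). Density differences kept by moves of 250 kb and splitting within 500 bp, alone or together, therefore do not account for the whole excess. With peaks moved by up to 50 kb the ratio was 1.45 (44.2% against 30.6%), and merging was not combined with that setting. Splitting of a site across gaps wider than 500 bp was not tested. Also open is whether close peaks follow closely spaced promoters or groups of binding motifs, which needs the genome of the build. No biological explanation was tested.

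Peaks were denser on X by the exact binomial test, but not past the adjusted threshold with 1-Mb windows permuted (adjusted permutation p = 0.0938). A few dense regions could carry the X excess. Without the 10 densest windows, 4 of them on X, the ratio of X to the other arms was 1.20 (bootstrap 95% interval 1.03 to 1.39). With all windows it was 1.25 (1.05 to 1.48). These intervals are not adjusted over arms, and the lower bound is too near 1 to decide. Removing windows by the value under test also narrows their spread and can by itself lower the X ratio, so the fall to 1.20 decides nothing. More narrow peaks passing the calling threshold on X is the other candidate. X held 24.0% of the arm peaks under 658 bp (308 of 1282) and 20.8% of the wider ones (269 of 1293, Fisher's exact test p = 0.0527). The X density ratio was 1.37 among the narrower peaks (adjusted p = 1.95e-05, exact binomial test) and 1.135 among the wider ones (adjusted p = 0.104). A larger X share of narrow peaks and a narrower X median are views of 1 difference, so neither is separate support for the other. The role of the calling threshold stays open, as the list has no score. Gene density of the arms was not tested.

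As another view of the larger X share among narrow peaks, the median X peak was narrower. Borders cut short by close neighbours do not account for it, since among peaks with no other within 5 kb the difference was -57.0 bp (permutation p = 0.00815, adjusted over 5 arms). Among peaks with another within 5 kb, the X median of 668.5 bp lay within the range of the other large arms (655 to 700 bp). The X difference among those peaks was not tested. A few regions with narrow peaks could still account for the narrower X, because window medians differed by -21.8 bp (permutation p = 0.318, adjusted over 5 arms). A lower X copy number in male larvae was not tested, as the labels do not give the sex of the larvae and the list holds no coverage.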

How the results depend on the processing

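The wider peaks (658 bp or more), merged peaks in the density and spacing results, placement between the first and the last peak and spacing without X were fixed before the data were examined; the other settings were chosen after seeing the data. Of 88 alternative values, 57 kept direction and side of the threshold, 22 lost significance and 9 changed sign. Values of density, X width and centromere ends were judged by p-values adjusted as in the reported result, or over the 4 tests of X against single arms. The spacing results kept both under every alternative run, with ratios of the median distance from 0.43 (X alone) to 0.78 (peaks moved by up to 50 kb) and of the share with a neighbour within 5 kb from 1.45 (peaks moved by up to 50 kb) to 3.59 (wider peaks). Density ratios lost significance as follows, and the cause was not tested. The window permutations use whole windows as units, of which chromosome 4 has 1. With all 1-Mb windows its test could not have passed at any count, so that loss says nothing about its density. With 1-Mb windows permuted, the ratios were 0.736 for 2L, 1.11 for 2R, 0.181 for chromosome 4 and 1.25 for X; with 2-Mb windows, 0.721 for 2L, 1.08 for 2R and 1.23 for X; without the 10 densest windows, 0.200 for chromosome 4 and 1.20 for X, while 2L was at 0.745 (adjusted permutation p = 0.0435). That setting removes windows by the value under test, which narrows their spread, so the p of 2L is no support for a lower density. Among the wider peaks X had 1.135, and 2R had 1.12 with merged peaks and 1.105 without chromosome 4. Without the 10 densest windows 2R turned to 0.992, as it holds 3 of them. Arms 3L and 3R, which were never past the threshold, crossed 1: 3L had 1.01 with 2-Mb windows and 1.001 without the densest windows, and 3R had 0.995 with lengths from the first peak, 0.991 with 1-Mb windows, 0.994 with 2-Mb windows, 0.993 without chromosome 4 and 0.949 without the centromere ends. The width difference of X lost significance at -28.5 bp with merged peaks, -21.8 bp with window medians, -23.0 bp against 2L, -42.0 bp against 2R and -24.0 bp against 3L. The depletion at centromere ends lost it at 3 Mb (0.819), with merged peaks (0.7005), without 2R (0.770), without 3L (0.693) and without X (0.668). The median width of peaks with a neighbour minus that of others was 29.0 bp at 5 kb and -8.0 bp at 2 kb, the latter with no detectable difference (permutation p = 0.57). No paired analysis was possible because the list has no value per library, and for the same reason no library could be left out. Alternatives for promoters, annotation classes, divergent genes, gene lists, motifs, words, scores and the assembly length of arms were not run.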

Other observations

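Peak width was compared between peaks with and without a close neighbour. The 1137 peaks with another within 5 kb had a median width of 678 bp, against 649 bp for the other 1433 (difference 29.0 bp, bootstrap 95% interval 5.0 to 55.0 bp, permutation p = 0.00806, chosen after seeing the data). The difference was 51 bp with a neighbour within 10 kb (permutation p = 1e-05, the smallest the resamples can give) and -8.0 bp with one within 2 kb, where none was detectable (permutation p = 0.57). The difference was 80.5 bp on 2L and 68.5 bp on X (adjusted permutation p = 0.0134 for both over 5 arms), 32 bp on 3R (0.277), 1.5 bp on 3L (0.925) and -17.0 bp on 2R (0.611). Whether the arms differ in this from each other was not tested. These permutations take peaks as independent, although close peaks come in pairs and runs by definition. The p-values may therefore be too small, and no permutation of windows or runs was made for them.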
